A study of Homo sapiens with 4 samples.

How the data were processed

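H3K27ac HiChIP was performed on 4 libraries, 1 for each combination of 2 breast carcinoma cell lines (MDA-MB-453 and MCF7) and 2 treatments (DMSO, or abemaciclib at 500 nM), each for 7 days. Per the labels' protocols, contacts were made by proximity ligation in fixed nuclei, chromatin was precipitated with an antibody against H3K27ac, and libraries were made on beads with the transposase Tn5. Only 1 library per group was deposited, and the labels do not say whether treatments were repeated or pooled before calling.

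The authors deposited 1 table of called interactions per library. The submitters' processing notes name HiC-Pro, Bowtie and the build hg19, and the deposited tables carry the name of the caller FitHiChIP and a q threshold of 0.05. The caller's version, the source of the H3K27ac peaks and any merging of nearby interactions are not given in the sources used here. Per the file headers, each line gives 2 bins, the contact count between them and the read coverage count of each bin, all as raw counts. Bins were 5 kb wide. Each line also holds a flag for bins in an H3K27ac peak, a coverage bias that the authors gave as a ratio to a mean coverage, and the expected contacts of the model as a signal in units of contacts. Per the file headers, a model probability (a fraction between 0 and 1), a p-value and a q-value follow. The deposited columns for mappability, GC content and restriction sites were 0 throughout and were not used. Interactions below the threshold are not listed, so a pair missing from a table has no contact count, and contact ratios exist only for pairs called in both libraries of a line. That selection favours pairs that are strong in both.

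The contact total was taken from the tables as a measure of depth. It was the median, over the lines of a table, of the expected contacts divided by the model probability. For the 2 DMSO tables, p-values were computed again from this contact total as the upper tail of a binomial distribution. Every deposited interaction was then called again. The abemaciclib tables were not checked in this way. The totals were 10517426 and 17241399 in MDA-MB-453 with DMSO and abemaciclib and 6727313 and 11621588 in MCF7. The q and p-values gave the number of pairs tested, 3192247, 3721149, 3025927 and 3290129 in the same order. Whether the total covers all contacts of a library or only those of the pairs tested is not stated, and mean coverage was higher with abemaciclib in peak bins and lower in other bins, so the total was not separated from enrichment. A deeper library can pass the threshold with a weaker contact, so counts of interactions depend on depth. Coverage divided by bias took 1 value for peak bins and 1 for other bins of a library, read here as their mean coverage. At bins listed in both libraries of a line the peak flag never differed (2021 bins in MDA-MB-453 and 2834 in MCF7). Between lines it differed at 44 of 684 common bins with DMSO. The mitochondrial genome held 2 interactions in each MDA-MB-453 library and 1 in each MCF7 library, and these were kept.

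Libraries were compared within each line, abemaciclib over DMSO, and then between lines. Interactions were shared when both bins were identical. Chance overlap came from 100 seeded draws in which every interaction was moved at random within its chromosome. The draws do not keep bins at peaks, so this chance level is low. Contact ratios were log2 ratios of counts. Their 95% intervals were exact (conditional binomial), and relative ratios had the median of all shared interactions of the line subtracted. Medians have 95% order-statistic intervals, and shares have exact binomial (Clopper-Pearson) ones. Contacts are read pairs, so the intervals of contact ratios cover counting error only. Those of medians and shares treat interactions or bins as independent. The interactions of a hub share a bin, so these intervals can be too narrow. No test across libraries was made. Within a line each group had 1 library, and a test with the lines as blocks, which leaves 1 residual degree of freedom, was not run. The fixed rule named the 10 bins with the largest increase and the 10 with the largest decrease in interactions per line, the 5 shared interactions with the highest and the 5 with the lowest relative ratio among those with at least 20 contacts over both libraries, and the 5 with the most contacts per library. Windows of 1 Mb, assigned by the middle of an interaction, and the region on chromosome 6 were added after seeing the data. The rule was written for genes with bins as the fallback. No hg19 annotation was used here, and the gene table at hand was of another build, so the planned counts per gene and per gene list were not made.

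Functions were tested on simulated data. In lists drawn from the DMSO contacts with 200 interactions changed by a fold of 4, 100% of these were placed above the median by their interval in both lines, against 1.19% of unchanged ones in MDA-MB-453 and 1.43% in MCF7. These draws held counting error only and applied no q threshold. The rates therefore need not carry over to pairs called in both libraries. Thinning kept each contact with the probability that matched the DMSO total and then repeated the authors' model and threshold, with the number of tests of the DMSO library. It cannot recover pairs that were not listed at full depth, so thinned counts can err on the low side. In simulated lists that were deepened and thinned back it kept 72.3% of the 2222 calls in MDA-MB-453 and 77.3% of the 5015 in MCF7. These lists held only pairs called with DMSO, unlike the abemaciclib lists, so the size of this loss need not carry over. Alternatives fixed before the data were examined were a q value below 0.01, at least 10 contacts, spans of 20 to 500 kb, equal numbers of interactions, leaving out the chromosome with the most interactions, a tolerance of 1 bin, sums in place of medians and summed contacts per bin. Thinning, pairs of peak bins only, and leaving out the mitochondrial genome with chromosome Y or chromosomes 17 and 20 were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.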

Results

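Chromatin contacts between acetylated regions were measured by H3K27ac HiChIP, an assay that joins DNA ends lying close together in fixed nuclei and then recovers, with an antibody, the joined fragments that carry histone H3 acetylated at lysine 27, a mark of active promoters and enhancers. The samples were 2 human breast carcinoma cell lines. MCF7 is a luminal line that expresses the estrogen receptor, and MDA-MB-453 is a luminal line with androgen receptor expression. Each line was treated for 7 days with 500 nM abemaciclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, or with the solvent DMSO. There was 1 library for each combination of line and treatment, 4 in all, so no difference has a replicate check. Whether a library pooled repeated treatments is not stated. Intervals of single contact ratios cover counting error only, and those of medians and shares treat interactions or bins as independent. All of them compare these libraries, not the treatments. The data list pairs of 5 kb bins on hg19 whose contacts exceeded a distance and coverage model at a q value below 0.05. The contact totals behind the model were 10517426 in MDA-MB-453 DMSO, 17241399 in MDA-MB-453 abemaciclib, 6727313 in MCF7 DMSO and 11621588 in MCF7 abemaciclib. The contact total with abemaciclib was thus 1.64 times that with DMSO in MDA-MB-453 and 1.73 times in MCF7, a measure of depth that was not separated from enrichment in peaks. Regions are given by position, because no gene annotation of hg19 was used here.

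The first comparison asked how the enhancer contacts of MDA-MB-453 differed after abemaciclib. The DMSO library held 2222 called interactions and the abemaciclib library 9697, which was 4.36 times as many. The bins with the largest differences in interaction number lay in a small number of hubs. The bin at chromosome 6, 10410001 to 10415000, anchored 9 interactions with DMSO and 141 with abemaciclib, and the adjoining bin from 10415001 anchored 7 and 117. With abemaciclib this pair of bins had 258 interactions, which reached from 8.06 Mb to 10.42 Mb, so that none extended past the hub on the side of higher positions. A second hub at chromosome 16, 54960001 to 54970000, had 52 and 41 interactions in its 2 bins with DMSO and 179 and 167 with abemaciclib. Another at chromosome 8, 116675001 to 116685000, had 25 and 16 against 146 and 99. When the abemaciclib list was reduced to the 2222 interactions of smallest q, these increases were smaller, 24 and 21 in the chromosome 6 bins, 49 and 53 in the chromosome 16 bins and 43 and 17 in the chromosome 8 bins, so that chromosome 6 no longer ranked first among them. With spans of 20 to 500 kb alone the increases were 14 and 7 in the chromosome 6 bins, 21 and 29 in the chromosome 16 bins and 48 and 35 in the chromosome 8 bins. Among pairs of peak bins alone, a choice made after seeing the data, they were between 6 and 16 in these bins.

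**Figure D1:**
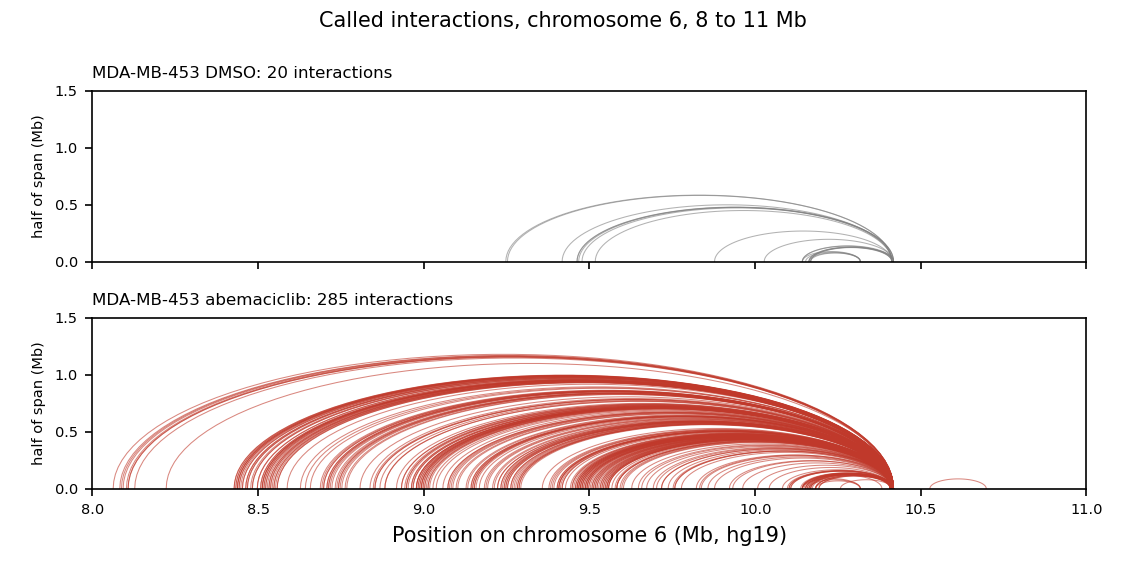
Called interactions of MDA-MB-453 from 8 to 11 Mb of chromosome 6 by position (horizontal axis, Mb on hg19), with 1 arc per interaction joining its bins, an arc height in Mb proportional to its span, and DMSO in grey and abemaciclib in red. The DMSO library had 20 interactions within this stretch and the abemaciclib library 285.

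Among the remaining bins with the largest increases in MDA-MB-453, chromosome 2 at 217555001 had 18 interactions with DMSO and 102 with abemaciclib. Chromosome 3 at 71630001 had 10 and 90, and chromosome 14 at 69255001 had 39 and 114. The bin at chromosome 5, 57750001 to 57755000, had 1 interaction with DMSO and 71 with abemaciclib, and its read coverage was 489 and 4200, a log2 ratio of 3.10 that was the highest of the peak bins listed in both libraries with a summed coverage of at least 200. These 10 bins all lay in H3K27ac peaks. Their coverage was higher with abemaciclib by 1.03 to 3.10 on the log2 scale, against a median of 0.73 over the 1593 peak bins listed in both libraries. The 10 largest decreases in the full lists were of 2 to 4 interactions. The bin at chromosome 11, 116965001 to 116970000, had 7 interactions with DMSO and 3 with abemaciclib, with a coverage of 1558 and 803. The bin at chromosome 20, 48805001, had 6 and 3. Of the 10 bins with the largest decreases, 3 lay on chromosome 6 between 26 and 28 Mb, and the one at 26250001 had 12 and 9 interactions. With spans of 20 to 500 kb alone, the change at each of these 3 bins was 0. In all, 8494 bins had more interactions with abemaciclib, 546 had fewer and 918 had equal numbers. With equal numbers of interactions in both lists, the increases at the 10 bins with the largest increases were between 17 and 53. The changes at the 10 bins with the largest decreases were between -10 and -2. In this setting 1314 bins had more and 1580 had fewer, a near balance that equal totals bring about.

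Of the 2222 interactions called with DMSO in MDA-MB-453, 1610 were called with abemaciclib for the identical pair of bins, a share of 72.5% (exact binomial 95% interval 70.5 to 74.3%). Moving the DMSO interactions at random within their chromosomes gave a median of 2 shared interactions and at most 5 in 100 draws. A further 8087 interactions were called with abemaciclib alone and 612 with DMSO alone. At the shared interactions the contact count was higher with abemaciclib, with a median log2 ratio of 0.58 (95% interval 0.55 to 0.62), against 0.71 between the contact totals. It was 0.79, above the depth ratio, with equal numbers of interactions or a tolerance of 1 bin, but both settings favour high abemaciclib counts. The first keeps only the abemaciclib interactions of smallest q, and the second takes the largest count among neighbouring abemaciclib pairs. They therefore cannot decide whether the ratio lay below the depth ratio. The value of 0.58 cannot decide it either. Its pairs had to be called in the DMSO library, of lower contact total, which can favour high DMSO counts. The ratio of observed over expected contacts had a median log2 of 0.09. Relative to the median log2 ratio of 0.58, the 5 shared interactions with the highest ratios all had 1 bin in common, chromosome 1 at 234740001 to 234745000. Its contacts with 235150001 to 235155000 numbered 11 with DMSO and 57 with abemaciclib, a relative log2 ratio of 1.79 (95% counting interval 0.84 to 2.87). The lowest ratio was at chromosome 20, where 30160001 to 30165000 and 30190001 to 30195000 shared 96 contacts with DMSO and 42 with abemaciclib, a relative log2 ratio of -1.78 (-2.34 to -1.24). The next lowest ratios were at chromosome 11, 116720001 with 116965001, and at chromosome 6, 26125001 with 27775001, both with a relative log2 ratio of -1.58. These extremes were picked from 1589 shared interactions with at least 20 contacts over both libraries, so their size is partly selected. Of all 1610 shared interactions, 125 lay above the median and 49 below it by an interval that excluded the median. Intervals of 95% exclude it for some unchanged interactions by counting error alone. In the simulation without a q threshold, 1.19% of unchanged ones lay above. The counts, and the smaller one above all, therefore need not all be changes.

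In MCF7 many of the interactions and most of the named bins lay on chromosomes 17 and 20. These chromosomes held 2680 of the 5015 interactions called with DMSO, which is 53.4% (52.0 to 54.8%), and 4639 of the 12454 called with abemaciclib, which is 37.2% (36.4 to 38.1%). After thinning to the DMSO contact total the abemaciclib share was 47.6% (46.8 to 48.2% over 20 draws), which is nearer to DMSO. In MDA-MB-453 they held 9.09% and 7.55%. Most of the difference between the MCF7 libraries lay elsewhere, since chromosomes 17 and 20 held 29.5% of the interactions called with abemaciclib alone. Without them, a setting chosen after seeing the data, MCF7 had 2335 and 7815 interactions, 3.35 times as many with abemaciclib, against 2.48 times over all chromosomes. MCF7 is known to carry amplified stretches of both chromosomes. The busiest bin, chromosome 17 at 57915001 to 57920000, anchored 260 interactions with DMSO and 531 with abemaciclib, and its coverage was 23729 and 86626. Its neighbour from 57920001 anchored 126 and 386, and the bin at 57180001 anchored 72 and 237. The first and the last of these bins, 735 kb apart, were also the pair with the most contacts in both MCF7 libraries. They shared 586 contacts with DMSO and 1962 with abemaciclib, where the model expected 1.63 and 1.77.

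Of the 10 MCF7 bins with the largest increases, those outside these chromosomes were both on chromosome 10. The bin at 3825001 to 3830000 had 20 interactions with DMSO and 132 with abemaciclib, and the bin at 8095001 to 8100000 had 46 and 122. On chromosome 20 the bin at 46410001 had 5 and 76 interactions and the bin at 52740001 had 10 and 73. Coverage at these 10 bins was higher with abemaciclib by 1.06 to 1.87 on the log2 scale, against a median of 0.60 over 1714 peak bins. The 10 largest decreases exceeded those in MDA-MB-453, and 9 of them lay on chromosomes 17 and 20. The bin at chromosome 17, 58675001, had 60 interactions with DMSO and 23 with abemaciclib, the bin at chromosome 20, 52195001, had 38 and 17, and the bin at chromosome 20, 46010001, had 20 and 5. When only pairs of peak bins were counted, a choice made after seeing the data, the decrease at chromosome 17, 58675001, became an increase of 1 interaction. So did the decrease at chromosome 17, 59475001, which had 69 and 51 interactions in all. The exception outside chromosomes 17 and 20 was chromosome 6 at 27775001 to 27780000, with 17 interactions and 7. In all, 8959 bins had more interactions with abemaciclib and 1277 had fewer. With 5015 interactions taken from both lists these were 2358 and 2298, a near balance that equal totals bring about. The increases at the 10 named bins were then between 10 and 221, with 221 and 179 at chromosome 17, 57915001 and 57920001. The changes at the bins with the largest decreases were between -49 and -10, with -46 at chromosome 17, 59475001, and -16 at chromosome 6, 27775001. With spans of 20 to 500 kb alone, the increases at chromosome 17, 57915001 and 57920001, were 73 and 66. The change at chromosome 6, 27775001, was then -1. Among pairs of peak bins alone, these values were 52, 49 and -9.

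In MCF7, 3190 of the 5015 DMSO interactions were also called with abemaciclib, a share of 63.6% (62.3 to 64.9%), where random shifts gave a median of 4 and at most 10. Abemaciclib alone had 9264 and DMSO alone 1825. Contacts at shared interactions had a median log2 ratio of 0.66 (0.63 to 0.69), against 0.79 between the contact totals. It was 0.85 with equal numbers or a tolerance of 1 bin, settings that both favour high abemaciclib counts, and 0.94 from summed contacts. All these values lay above the depth ratio. The value of 0.66 needs a call in the DMSO library, of lower contact total, which can favour high DMSO counts. The ratio of observed over expected contacts had a median log2 of 0.09. The highest relative ratio was between adjoining bins of chromosome 20, 47895001 to 47905000, with 39 and 366 contacts and a relative log2 ratio of 2.57 (2.09 to 3.09). The next 4 all joined chromosome 17 at 57915001 to bins between 56700001 and 56950000, with 8 to 10 contacts with DMSO and 56 to 62 with abemaciclib. The lowest was at chromosome 20, 360001 to 365000 with 370001 to 375000, with 66 contacts and 22 and a relative log2 ratio of -2.24 (-3.01 to -1.53). Chromosome 17 at 41380001 with 41400001 followed at -2.00. Among the 5 lowest, 2 joined chromosome 6 at 27775001 to bins at 27110001 and 27115001. Relative ratios were not corrected for the coverage of the bins. The log2 coverage ratio was 3.08 at chromosome 20, 47900001, 1.87 at chromosome 17, 57915001, and -1.90 at chromosome 20, 360001. It was 0.16 at chromosome 6, 27775001. Relative to the median, 508 of the 3190 shared interactions lay above and 218 below by an interval that excluded it. Some of these are due to counting error alone. In the simulation without a q threshold, 1.43% of unchanged ones lay above.

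Contact ratios relative to the median of the line were also taken over 1 Mb windows with at least 10 shared interactions, 35 in MDA-MB-453 and 47 in MCF7. The windows named here were chosen after their values were seen. In MDA-MB-453 the highest were chromosome 14 from 68 to 69 Mb, with a median relative log2 ratio of 0.48 (95% interval 0.17 to 0.65), and chromosome 1 from 234 to 235 Mb, with 0.38 (0.27 to 0.62). The lowest was chromosome 16 from 30 to 31 Mb with -0.36 (-0.58 to -0.19). In MCF7 the highest were chromosome 10 from 3 to 4 Mb, with 0.65 and an interval that included 0 (-0.02 to 0.93), and chromosome 7 from 1 to 2 Mb, with 0.62 (0.04 to 1.09). The lowest was chromosome 16 from 46 to 47 Mb with -1.26 (-1.57 to -1.11), a window beside the centromere. Chromosome 11 from 69 to 70 Mb had -0.66 (-0.77 to -0.53) over 41 shared interactions and was listed with 56 interactions with DMSO and 61 with abemaciclib. Chromosome 17 from 48 to 49 Mb was higher than the median in both lines, with 0.32 (0.17 to 0.57) in MDA-MB-453 and 0.58 (0.45 to 0.77) in MCF7. It was 1 of only 3 windows with the same sign in both lines, out of 8 with at least 10 shared interactions in both.

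The region of chromosome 6 from 26 to 28 Mb held 229 interactions of the MDA-MB-453 DMSO list, 10.3% of it (9.07 to 11.6%), and its windows ranked 1 and 3 among all 1 Mb windows of that list. With abemaciclib it held 399, which was 4.11% (3.73 to 4.53%). Its 171 shared interactions had a median relative log2 contact ratio of -0.19 (-0.30 to -0.08), with 105 of them below the median of all shared interactions. Of 33 other windows in this line, 4 had a median at or below this value. Coverage at the 51 peak bins of the region did not lie below that of other peak bins, with a relative log2 median of 0.15 (-0.09 to 0.27). In MCF7 the same region had 61 interactions with DMSO and 22 with abemaciclib, or 1.22% and 0.177% of the lists. Only 6 were shared, and all 6 lay below the median, with a median relative log2 ratio of -1.34 (-1.98 to -0.59). In MCF7 coverage at the 16 peak bins of the region did lie below that of other peak bins, with a relative log2 median of -0.46 (-0.94 to -0.18). This region was singled out after its values were seen.

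**Figure D2:**
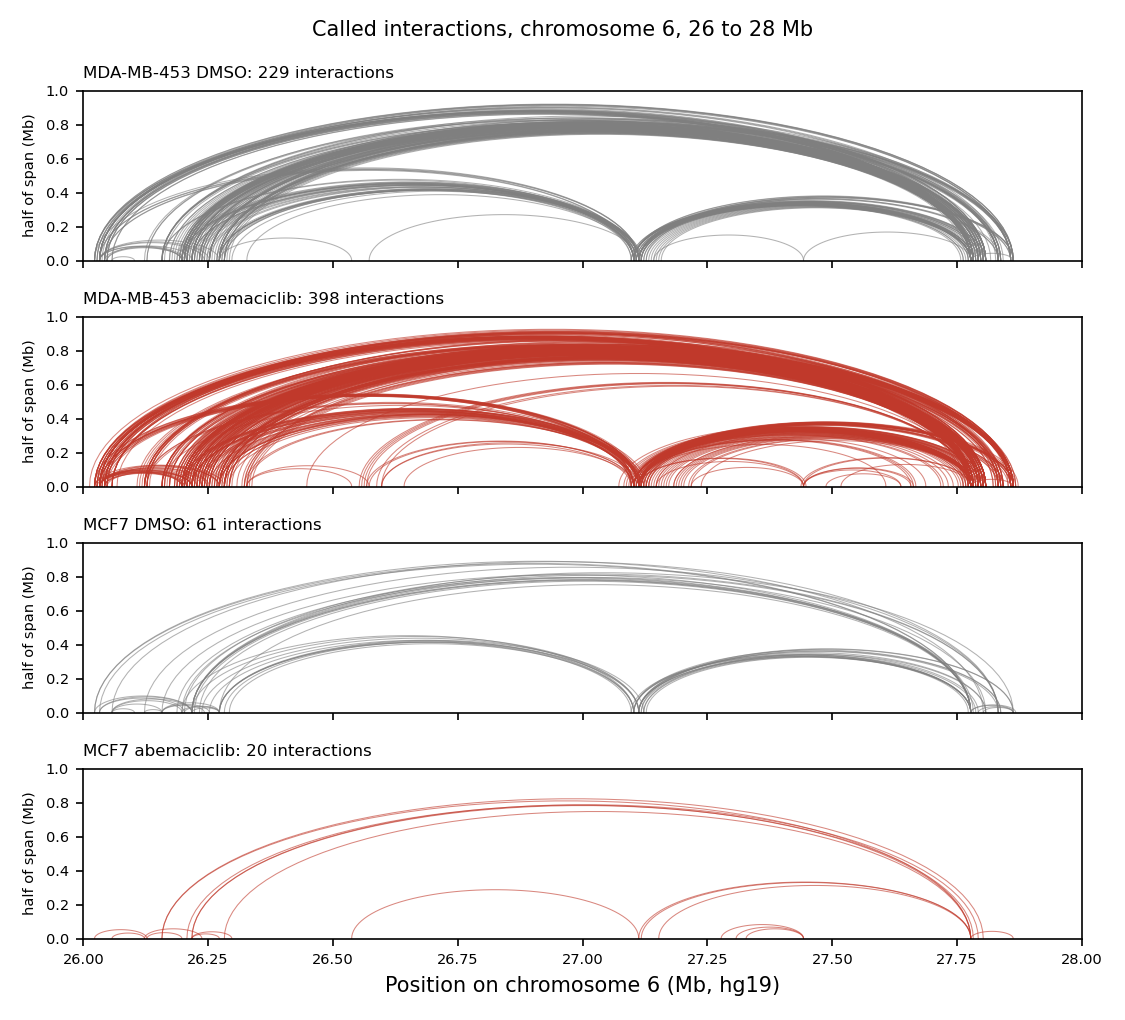
Called interactions with both bins between 26 and 28 Mb of chromosome 6 in the 4 libraries by position (horizontal axis, Mb on hg19), with 1 arc per interaction joining its bins, an arc height in Mb proportional to its span, and DMSO in grey and abemaciclib in red. With DMSO and abemaciclib there were 229 and 398 arcs in MDA-MB-453 and 61 and 20 in MCF7.

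When the contacts of each abemaciclib library were thinned to the contact total of its DMSO library and called again, an alternative chosen after seeing the data, MDA-MB-453 kept a median of 4660.5 interactions over 20 draws, 2.10 times the DMSO count. MCF7 kept 6079, which was 1.21 times the DMSO count, and 1.36 times outside chromosomes 17 and 20. The mean coverage of H3K27ac peak bins over that of other bins was 4.10 in MDA-MB-453 DMSO and 7.35 in MDA-MB-453 abemaciclib. It was 2.94 in MCF7 DMSO and 6.86 in MCF7 abemaciclib. Over all anchor bins listed in both libraries of a line, the median log2 coverage ratio was 0.58 (0.56 to 0.62) in MDA-MB-453 and 0.08 (0.04 to 0.13) in MCF7, without correction for depth. In MDA-MB-453, coverage in peaks had a median log2 ratio of 0.73 (0.69 to 0.75) and other bins one of 0.05 (0.02 to 0.09). In MCF7 these were 0.60 (0.55 to 0.64) and -0.43 (-0.47 to -0.40).

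**Figure D3:**
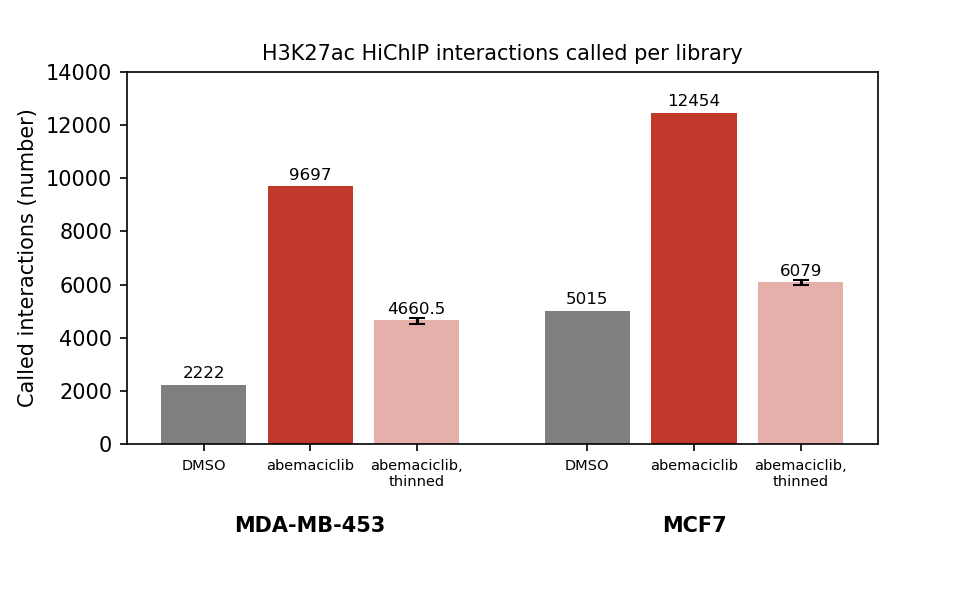
Number of interactions called per library (vertical axis) for each line and treatment, with 1 library per bar, and pale bars for the median of 20 thinnings of the abemaciclib library to the DMSO contact total, whose whiskers span the lowest and highest draw. The thinned counts were 4660.5 and 6079, against 2222 and 5015 with DMSO.

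**Figure D4:**
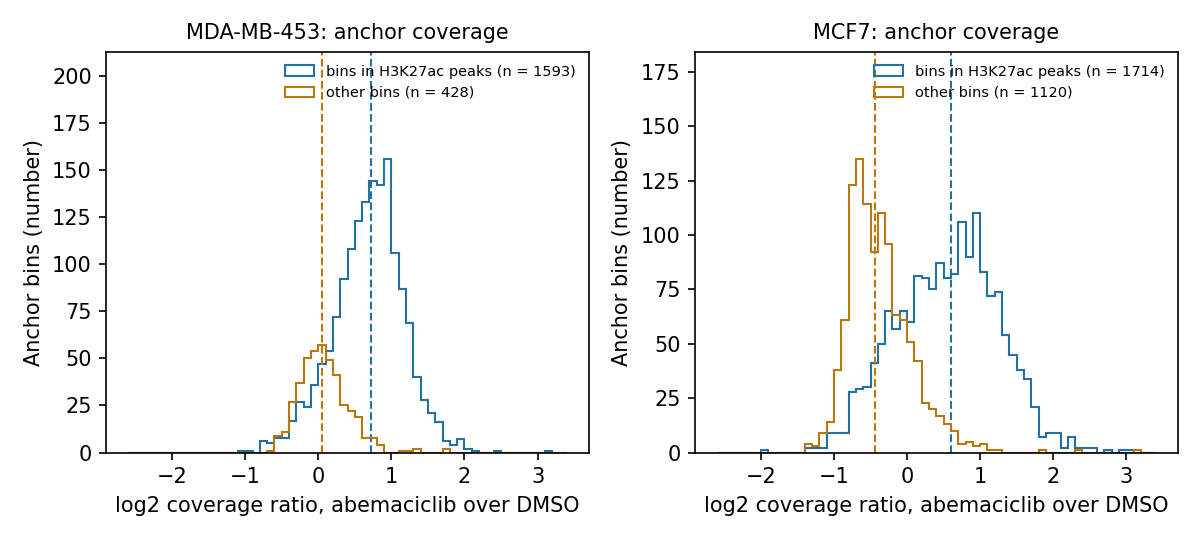
Distribution of the log2 coverage ratio, abemaciclib over DMSO (horizontal axis), over anchor bins listed in both libraries of a line (vertical axis, number of bins). Blue is bins in H3K27ac peaks, orange is other bins, and dashed lines mark the medians, which were 0.73 and 0.05 in MDA-MB-453 and 0.60 and -0.43 in MCF7.

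The span of the interactions had a median of 250 kb (240 to 260 kb) in MDA-MB-453 DMSO and 290 kb (280 to 295 kb) in MDA-MB-453 abemaciclib. In MCF7 it was 190 kb (185 to 195 kb) and 195 kb (190 to 200 kb). Among pairs of peak bins alone the order turned in both lines, with 185 kb and 165 kb in MDA-MB-453 and 135 kb and 115 kb in MCF7. Interactions with both bins in H3K27ac peaks made up 72.1% (70.2 to 74.0%) of the MDA-MB-453 DMSO list and 51.0% (50.0 to 52.0%) of the abemaciclib list. In MCF7 the shares were 48.5% (47.1 to 49.9%) and 49.4% (48.5 to 50.3%). Among interactions of MDA-MB-453 called with abemaciclib alone, 47.1% joined 2 peak bins, against 70.4% of the shared ones.

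The last comparison asked which contacts the lines had in common. Hubs differed between them. The window of chromosome 16 from 54 to 55 Mb held 116 and 419 interactions in MDA-MB-453 with DMSO and abemaciclib, and 2 and 4 in MCF7. The window of chromosome 17 from 58 to 59 Mb held 373 and 946 in MCF7 and 0 in both MDA-MB-453 lists. It was among the 5 busiest MCF7 windows with both treatments. Anchor bins outside peaks in those windows had 6.68 and 6.60 times the median coverage of such bins elsewhere. Copy number was therefore not separated from this difference. Other hubs occurred in both lines. Chromosome 10 from 8 to 9 Mb held 36 and 127 interactions in MDA-MB-453 and 62 and 149 in MCF7, chromosome 8 from 102 to 103 Mb held 15 and 125 and 67 and 146, and chromosome 8 from 116 to 117 Mb held 27 and 143 and 30 and 85. With DMSO 374 interactions were called in both lines for the identical pair of bins, and with abemaciclib 1655, where random shifts gave at most 3 and 7. Of the interactions called with abemaciclib alone, 827 were common to both lines, against at most 4 in random shifts and 22.8 expected of independent lists drawn from the pairs tested. Of those called with DMSO alone, 26 were common, against at most 1 in random shifts. The larger number with abemaciclib did not hold with equal numbers of interactions per line, where 77 abemaciclib-only and 82 DMSO-only interactions were common. After thinning to the DMSO contact total these were 189 and 64. Crossed lists overlapped too, with 139 interactions that were abemaciclib-only in MDA-MB-453 and DMSO-only in MCF7, and 47 the other way. Random shifts and independent lists do not keep interactions at peaks. These overlaps alone therefore do not show that both lines changed in the same direction.

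The coverage and contact ratios of the 2 lines, which share no control library, were correlated in 2 ways. Over 449 peak bins listed in all 4 libraries, the log2 coverage ratios relative to the median of each line had a Pearson correlation of 0.52 and a Spearman correlation of 0.46 between lines, and 68.4% of the bins had the same sign. After removing the ranks of the DMSO coverage in both lines, the Spearman correlation was 0.41. Over the 242 interactions called in all 4 libraries, the contact ratios had a Pearson correlation of 0.44 and a Spearman correlation of 0.36, with 57.4% of the same sign. These correlations are across bins or interactions, which are not independent replicates, so no p-value is given.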

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

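The values here were picked because the abemaciclib library lay above the DMSO library in 1 line and below it in the other. With 1 library per group none of these differences between lines was tested. The thinning and the window were chosen after the values were seen. The share of interactions with both bins in peaks changed by -21.1 percentage points in MDA-MB-453 and by 0.896 in MCF7, where the intervals of the MCF7 libraries overlapped. Thinning to the DMSO contact total left the abemaciclib shares at 52.0% and 49.8%. The share spanning 20 kb or less changed by -0.973 points in MDA-MB-453, where the intervals of the libraries overlapped (5.37 to 7.44% and 4.93 to 5.84%), and by 2.83 in MCF7, from 4.39%. After thinning the abemaciclib shares were 4.57% in MDA-MB-453 (4.19 to 4.96% over the draws), further from the 6.35% of DMSO, and 5.68% in MCF7, closer to DMSO, so the opposite directions remained. The share spanning over 1 Mb changed by -0.850 points in MDA-MB-453, where the intervals overlapped (8.73 to 11.3% and 8.53 to 9.69%), and by 1.36 in MCF7, from 6.26%. After thinning the abemaciclib shares were 10.1% in MDA-MB-453 (9.83 to 10.5% over the draws, against 9.95% with DMSO) and 9.53% in MCF7, so the opposite directions did not hold. The window of chromosome 17 from 66 to 67 Mb had a median relative log2 contact ratio of 0.22 (0.08 to 0.50) over 22 shared interactions in MDA-MB-453 and of -0.77 (-1.02 to -0.19) over 13 in MCF7. It was 1 of 8 windows with at least 10 shared interactions in both lines, of which 3 had the same sign in both.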

How the results depend on the processing

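No paired analysis was possible within a line because each group had 1 library. A fit over both lines with the line as a block, which leaves 1 residual degree of freedom, was not made. The planned counts at genes, also with start sites within 5 kb, and the gene lists were not run for lack of an hg19 annotation. Thinning, pairs of peak bins and leaving out chromosomes 17 and 20 were chosen after seeing the data. More interactions were called with abemaciclib than with DMSO under every filter and the thinning, from 2.10 to 4.54 times as many in MDA-MB-453 and from 1.21 to 3.35 times in MCF7; the cause of the shifts below was not tested except where the setting itself removes interactions. With a q value below 0.01 the median span was 265 kb and 300 kb in MDA-MB-453 (DMSO, then abemaciclib), 349 MDA-MB-453 bins had fewer interactions, the MCF7 median log2 contact ratio was 0.70, and 17 DMSO-only and 547 abemaciclib-only interactions were common to both lines. With at least 10 contacts the median span was 270 kb in MDA-MB-453 abemaciclib and 170 kb in both MCF7 libraries. With spans of 20 to 500 kb it was 180, 215, 155 and 165 kb in the order of the libraries, MDA-MB-453 abemaciclib kept 6459 interactions, 1069 were shared in MDA-MB-453, its coverage ratio was 0.63 and the MCF7 contact ratio 0.58. Without the chromosome with most interactions the spans were 215, 270, 165 and 165 kb, the MCF7 contact ratio was 0.55 and its coverage ratio 0.16. With equal numbers of interactions the abemaciclib spans were 345 kb in MDA-MB-453 and 225 kb in MCF7, and MDA-MB-453 shared 968. The contact ratios were then 0.79 and 0.85 and the MDA-MB-453 coverage ratio 0.63. Bins with more and fewer interactions were 1314 and 1580 in MDA-MB-453 and 2358 and 2298 in MCF7. Equal totals bring gains and losses near balance, so this setting cannot show whether the excess of gains holds. In the same setting 82 DMSO-only and 77 abemaciclib-only interactions were common to both lines. With a tolerance of 1 bin the contact ratios were 0.79 and 0.85. From sums the contact ratios were 0.67 and 0.94 and the coverage ratios 0.86 and 0.50. Pairs of peak bins alone gave 4942 interactions in MDA-MB-453 abemaciclib, 2434 in MCF7 DMSO and 6156 in MCF7 abemaciclib, spans of 185, 165, 135 and 115 kb, 1618 shared in MCF7, coverage ratios of 0.72 and 0.57, more interactions at 4544 MDA-MB-453 and 5127 MCF7 bins, fewer at 643 MCF7 bins, and 402 common abemaciclib-only interactions; the abemaciclib span was then below that of DMSO in both lines, and the losses at chromosome 17, 58675001 and 59475001, became gains of 1 and 1. Without chromosomes 17 and 20, MCF7 had 2335 and 7815 interactions. Thinning gave 4660.5 interactions (2.10 times DMSO) with a span of 305 kb in MDA-MB-453, 6079 (1.21 times) with 210 kb in MCF7, and 64 DMSO-only and 189 abemaciclib-only interactions common to both lines. Of the main values recomputed, 113 stayed within 1.5 times the count or the interval of the median and 65 moved. No median ratio changed sign. The contact ratios, below the depth ratios of 0.71 and 0.79 in the full lists, lay above them in MCF7 from sums. They also lay above them with equal numbers or a tolerance of 1 bin, settings that both favour high abemaciclib counts. The ratios of the full lists need a call in the DMSO library, which can favour high DMSO counts. Of the values for single bins and interactions, 273 stayed, 138 moved and 2 changed sign. Of those that moved, 40 were changes in summed contacts, another unit whose size cannot be compared and which kept their sign. A further 12 were at bins on the chromosome left out. Leaving out the mitochondrial genome and chromosome Y, which removes few interactions, gave 22 of the main values that stayed and 60 of the single values that stayed. A filter changes only the median subtracted from the ratio of a named interaction. Named interactions dropped by a setting were not counted. Depth limits the lists: contacts of pairs below the threshold are not given.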

Other observations

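The bins named first, and the tests of enrichment, of treatment as the origin of the MCF7 concentration and of dilution in MCF7, were chosen after the result was seen. Peak bins with extreme coverage ratios differed in their numbers of interactions. In MDA-MB-453 the bin at chromosome 11, 65270001 to 65275000, had a coverage of 1910 with DMSO and 10443 with abemaciclib and anchored 2 and 9 interactions, and the bin at chromosome 3, 4720001, had 608 and 2646. In MCF7 the bin at chromosome 20, 47900001 to 47905000, had a coverage of 252 and 2135 with 1 interaction in each library, the bin at chromosome 12, 13045001, had 775 and 5377 with 2 and 15 interactions, and the bin at chromosome 3, 150125001, had 886 and 5281 with 5 and 23. The lowest in MCF7 was chromosome 20 at 360001 to 365000, with 1363 and 364. Of the 5 interactions with the most contacts in MDA-MB-453 DMSO, 4 were beside centromeres, among them chromosome 10, 42385001 with 42395001 (340 contacts, and 210 with abemaciclib), and chromosome 16, 46390001 with 46405001 (326 and 227). The other was chromosome 11, 65260001 with 65265001, with 235 contacts, 1.32 times those expected, which was not called with abemaciclib. The coverage of its bin at 65260001 was 1197 with DMSO and 3813 with abemaciclib. A pair that was not called has no contact count, so fewer contacts cannot be read from this. In MDA-MB-453 abemaciclib the most contacts were at chromosome X, 153600001 with 153605001, with 1152 where the model expected 1016.

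The first pattern is the larger number of interactions with abemaciclib. Depth alone is argued against in MDA-MB-453, where calling at the DMSO contact total, taken as the depth, still gave 2.10 times the DMSO count (2.04 to 2.13 over 20 draws). In MCF7 the same test gave 1.21 times (1.19 to 1.23), within the bound of 1.5 set before, so depth is a candidate explanation for part of that difference. How large a part stays open, since thinning cannot recover pairs that were not listed at full depth. Simulated lists with no change kept 77.3% of the MCF7 calls after thinning. They held only pairs called with DMSO, so this value need not apply to the abemaciclib list. The ratio of peak to other coverage was higher with abemaciclib in both lines, by a factor of at least 1.79, and a better precipitation cannot be told apart from a gain of acetylation, because each treatment had 1 library, so an effect of abemaciclib stays open.

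The second pattern is the concentration of MCF7 interactions on chromosomes 17 and 20. Copy number is a candidate explanation: in the 5 windows of 1 Mb with most interactions, anchor bins outside peaks had a median coverage of 1142 with DMSO against 171 elsewhere, a ratio of 6.68, and the ratio was 6.60 with abemaciclib. In MDA-MB-453 the same measure was 1.27 and 1.16 for its own 5 busiest windows. Treatment is argued against, since 53.4% of the interactions were already on these chromosomes with DMSO. These bins were listed because they were called, and whether the amplified DNA is also rearranged was not tested.

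The third pattern is chromosome 6 from 26 to 28 Mb. In MDA-MB-453 its smaller share may reflect interactions called elsewhere: the shared interactions there had a median relative log2 contact ratio of -0.19, and the thinned abemaciclib list held a median of 239 interactions in the region against 229 with DMSO. The region made up 5.15% of the thinned list and 10.3% of the DMSO list. These values do not say why it gained less than other regions. In MCF7 dilution alone is argued against, since the relative ratio was -1.34 (-1.98 to -0.59) over 6 shared interactions, where dilution predicts values near 0. A treatment effect common to both lines cannot be told apart from chance between single libraries, and the MDA-MB-453 value fell just short of the bound of -0.2 set before that test, with an interval of -0.30 to -0.08. A lower number of interactions was seen in MCF7 alone, 22 against 61, while MDA-MB-453 had 399 against 229.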
